A study of Danio rerio with 18 samples.

How the data were processed

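RNA was measured in whole zebrafish embryos irradiated 30 h after fertilization with X-rays, to a total dose of 30 Gy at 5 Gy per min. Untreated embryos carry the same stage label. The labels do not say when they were collected, so a comparison with untreated embryos may include a difference in age at collection. Per the labels, libraries were made from total RNA with poly(A) selection and sequenced in pairs of reads, with a read length that differed between sequencing centres and is not given per library. The genotypes were p53 wild type (untreated and 3 h after irradiation), p53 mutant (untreated, 1 h and 3 h) and a triple mutant of puma, noxa and p21 (untreated, 1 h, 2 h and 3 h), which gives 9 groups of 2 libraries and 18 libraries. The labels do not say whether the 2 libraries of a group come from separate clutches or pools of embryos. The p values below therefore measure the spread between libraries, whatever its source.

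The authors deposited 3 tables, 1 per genotype, of TPM values, transcript abundances per gene corrected for gene length and scaled to a fixed sum per library. Each column was checked to sum to 1000000, within 1, over 32057 genes. The submitters' processing notes name STAR 2.7.3a, HTSeq 0.12.3, DESeq2 1.42.1, RSEM 1.3.3, R 4.3.3 and the build GRCz11, without saying what each tool did. The annotation release and the filters are not stated. TPM values hold no read counts, so the depth of each library is unknown and no counting interval or detection floor was computed. A gene listed at 0 may have been expressed below the depth, and the report gives no fold against a group in which every library is at 0. Where a difference between responses rests on such a group, the fitted value depends on the pseudocount, and this is said beside it.

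Gene identifiers were matched to symbols with a gene name table, which gave a symbol for 28988 of the 32057 genes. Of these, 14504 carry a symbol in capitals in the human style, and 1651 such symbols belong to more than 1 gene. Those are printed with their identifier. Gene coordinates were not used here.

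Values were taken as log2(TPM + 1). Genes with at least 1 TPM in at least 2 libraries were kept, which left 18575 genes, 17908 of them with a symbol. A single model over the 9 groups was fitted with limma 3.58.1 in R 4.3.3, with the spread modelled as a trend on the mean (9 residual and 2.87 prior degrees of freedom). The model made 11 comparisons. Of these, 6 set an irradiated group against the untreated group of its genotype, 1 set 3 h against 1 h in the triple mutant, and 4 were differences between the responses of 2 genotypes. Each comparison lies within a table, or subtracts changes that do, so a constant offset between tables cancels. Untreated levels are set side by side across genotypes without a test, because genotype, table and sequencing run cannot be separated. Tests were two-sided, p values were adjusted by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05.

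All groups share 1 estimate of the spread per gene. The library pairs differed in agreement, so the shared spread is too small for some groups and too large for others. Each count of a comparison within a genotype is therefore given beside that of a separate fit within its table. The differences between responses span 2 tables and have no such fit. On data simulated with the same group sizes, with 18575 genes and 100 of them shifted by 2 on the log2 scale, 65%, 67% and 68% of the shifted genes were called in the wild type, the p53 mutant and the triple mutant at 3 h. For a shift of 1, the shares were 21%, 23% and 35%. The unshifted genes called numbered 4, 5 and 3. With the spread of each group set to the one observed, they numbered 62, 11 and 1. The simulated errors were independent between genes and libraries. Deviations that many genes or libraries share were left out, so these numbers may be too low for the real data.

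Before the data were examined, 27 gene lists were fixed (p53 targets, processes of the cell cycle, damage and stress, and marker genes of embryonic tissues). They were tested with limma's camera, with a preset correlation between genes of 0.01, adjusted over the lists within each comparison. Members were counted as called over all genes and adjusted over the list alone. An additional list of hypoxia response genes was written after 2 of its genes had been seen among the calls. Overlaps between sets of called genes were tested with two-sided Fisher exact tests across genes. For overlaps that share untreated libraries, 100 simulations gave the overlap when no gene changes in any group. They do not measure what the shared libraries add when genes do change. The p53-dependent induced genes were defined as those called higher at 3 h in the wild type and in the triple mutant, and called higher in the triple mutant response than in the p53 mutant response.

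Named genes follow a rule also fixed before the data were examined. It takes the genes of the genotypes and the series title with mdm2, and for each comparison with untreated the 10 largest rises and the 10 largest falls among called genes with a symbol. These need a mean of at least 5 TPM in a group and no overlap between the libraries of the groups. For each difference between responses it takes the 10 largest in each direction. It adds up to 4 members per list with the smallest p, the 20 p53-dependent genes with the largest mean change, and 5 genes for each time of first call in the triple mutant. The text names fewer than the rule allows. A gene chosen by this rule is not reported here.

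Alternatives covered the pseudocount (0.1 and 5 TPM), the filter (none, and a mean of 5 TPM), scaling of each library by the median ratio to the gene-wise geometric mean, quantile normalization, a separate fit per table, a replicate block, robust and weighted fits, an added log2 change of 1, and leaving out each library in turn. Alternatives chosen after seeing the data left out libraries by their content of 5.8S ribosomal RNA, crossed the replicate numbers of the wild type, and removed mitochondrial transcripts. For the p53 mutant at 1 h alone, 5.8S content was also added as a block. Figures were drawn from the resulting tables.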

Results

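Transcript levels were measured in whole zebrafish embryos after ionizing radiation, in 3 genotypes and at up to 3 times, with 2 libraries in each of 9 groups. The p53 mutant lacks the transcription factor that is activated by DNA damage. The triple mutant (puma, noxa and p21) keeps p53 but lacks effectors of p53, namely the cell death genes bbc3 (puma) and pmaip1 (noxa) and the cell cycle inhibitor cdkn1a (p21). The series title asks about p21, ccng1, foxo3b and fbxw7 in p53-dependent arrest of the cell cycle. Depth per library is unknown from TPM values. The number of genes with at least 1 TPM ranged from 14057 in replicate 1 of the p53 mutant at 1 h to 17419 in replicate 2 of the untreated wild type.

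Libraries of a group correlated across genes at r = 0.991 to 0.994 in the triple mutant and in the p53 mutant at 3 h, and at 0.987 in the wild type at 3 h. The correlation was 0.963 in the untreated p53 mutant, 0.944 in the untreated wild type and 0.907 in the p53 mutant at 1 h. The pairs with the lowest agreement each joined a library with 304 to 631 TPM of 5.8S ribosomal RNA and a library with 13.6 to 52.8 TPM. The other 12 libraries were listed at 0 for this RNA. In the wild type and the p53 mutant, 3 h and untreated libraries therefore differ in 5.8S content as well as in treatment. Mitochondrial transcripts made up 1.15% to 8.06% of TPM in the 18 libraries.

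**Figure D1:**
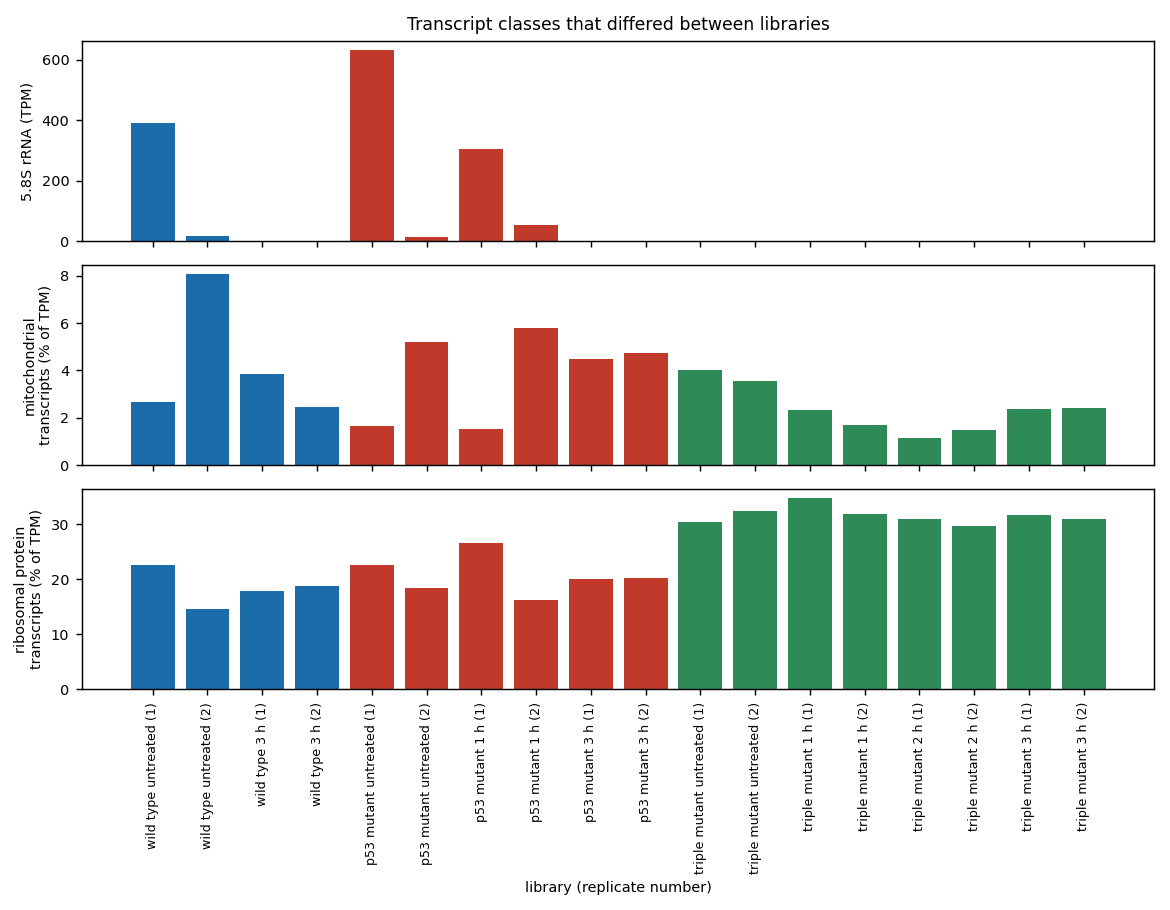
Bars give, for each of the 18 libraries, the TPM of 5.8S ribosomal RNA and the percent of TPM in mitochondrial and in ribosomal protein transcripts, coloured by genotype. The 6 libraries with 5.8S RNA above 0 are the untreated wild type and the untreated and 1 h p53 mutant libraries.

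The p53 pathway genes mdm2, cdkn1a and bbc3 rose in the wild type and the triple mutant, and no such rise was called in the p53 mutant. The p53 inhibitor mdm2 (ENSDARG00000033443) went from 43.7 ± 16.8 TPM (SD, n = 2) in untreated wild type embryos to 1015 ± 16.9 TPM at 3 h, from 54.0 ± 1.1 to 764 ± 59.5 TPM in the triple mutant, and from 39.0 ± 18.6 to 53.2 ± 5.64 TPM in the p53 mutant. The deleted genes of the triple mutant still gave transcripts, so their levels do not check the genotype. Its cdkn1a (ENSDARG00000076554) went from 2.73 ± 1.15 to 58.9 ± 9.79 TPM at 3 h and its bbc3 (ENSDARG00000069282) from 0.650 ± 0.099 to 34.6 ± 1.09 TPM.

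**Figure D2:**
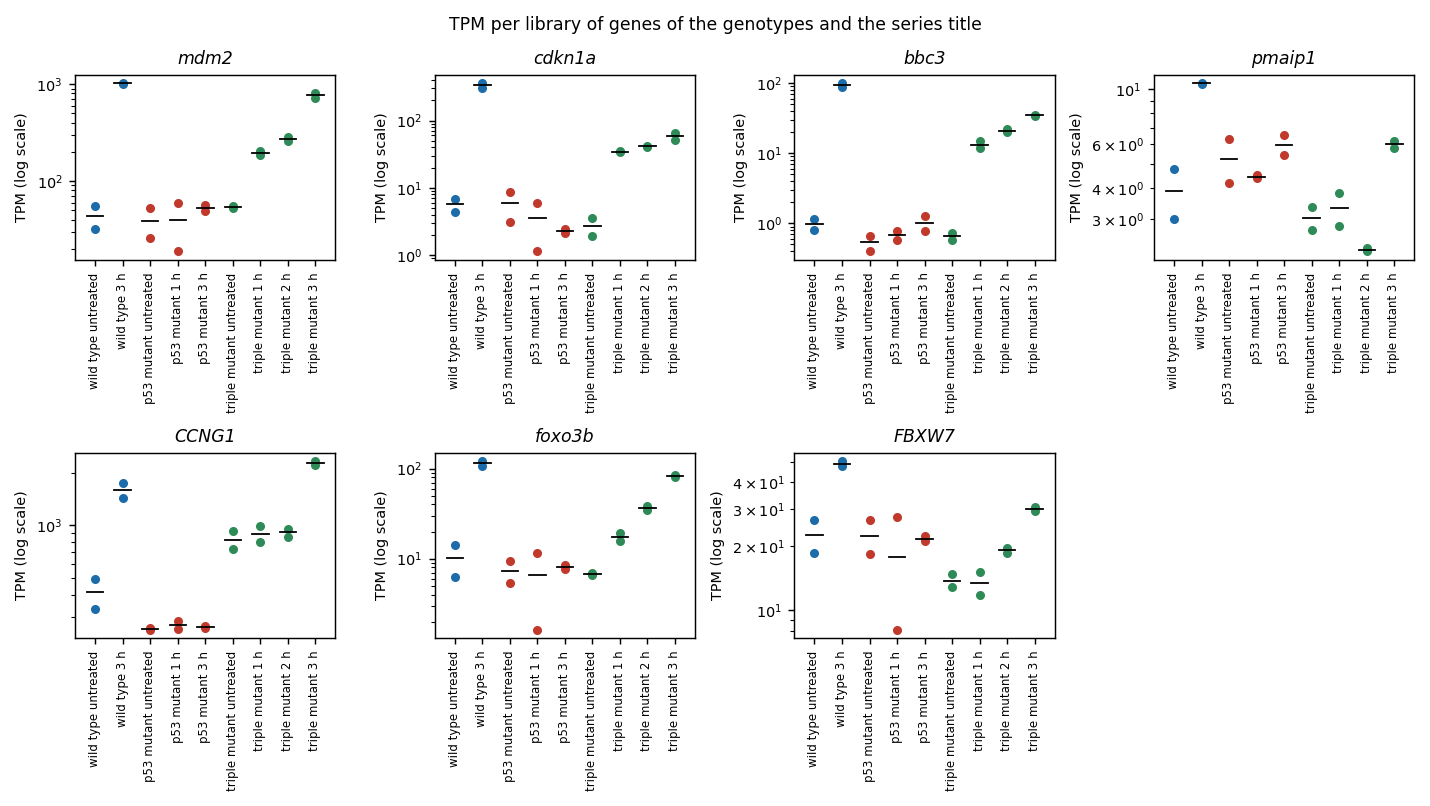
Points give the TPM of each library on a log axis and lines the mean of each group of 2, for mdm2, cdkn1a, bbc3, pmaip1, CCNG1, foxo3b and FBXW7. In the triple mutant mdm2 goes from 54.0 TPM untreated to 764 TPM at 3 h, and in the p53 mutant from 39.0 to 53.2 TPM.

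In irradiated wild type embryos at 3 h, si:dkey-204l11.1 rose by 5.93 (SE 0.155, adjusted p = 1.51e-09) on the log2 scale. The cell cycle inhibitor gene cdkn1a rose by 5.66 (SE 0.488, adjusted p = 4.04e-05), the cell death gene bbc3 by 5.59 (SE 0.198, adjusted p = 1.83e-08) and mdm2 by 4.56 (SE 0.437, adjusted p = 9.31e-05). Further large rises were those of PHLDA3, a p53 target, by 4.33 (SE 0.146), RBL2, a member of the retinoblastoma family, by 4.19 (SE 0.32), DDIT4, an inhibitor of growth signalling, by 4.01 (SE 0.173), and GADD45A (ENSDARG00000043581), a damage-induced inhibitor, by 3.90 (SE 0.24). Among the title genes, foxo3b (ENSDARG00000042904) rose by 3.45 (SE 0.551, adjusted p = 0.00504) and CCNG1 (ENSDARG00000076667), which encodes cyclin G1, by 1.96 (SE 0.193, adjusted p = 0.000117). FBXW7 (ENSDARG00000060994), a ubiquitin ligase subunit, had a change of 1.11 (SE 0.395) that missed the threshold (adjusted p = 0.157), with both irradiated libraries above both untreated ones. The change of pmaip1 (ENSDARG00000089307), 1.27 (SE 0.227, adjusted p = 0.00992), lost its call under either rescaling, in the fit within the table, with array weights, and without WT 3 h replicate 1 or 2 or untreated replicate 2. Its adjusted p reached 0.271 within the table, where that of CCNG1 was 0.0517.

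In total, 702 of 18575 genes were called in the wild type, 578 higher and 124 lower, and 333 of them changed by at least 1 on the log2 scale. The median change of all genes was 0.23 on the log2 scale, so the split of rises and falls is relative to that shift. With median-of-ratios scaling the calls were 333 higher and 326 lower, and with quantile normalization 450 and 369. The fit within the wild type table called 91 genes, 72 higher and 19 lower, of which 82 were among the 702. Without WT 3 h replicate 2 the count was 172 and without p53 mutant 1 h replicate 2 it was 1900, and it moved by more than 1.5 times for 13 of the 18 libraries. Without the 3 libraries of high 5.8S content it was 5247, and without the 3 of low content 10552.

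**Figure D3:**
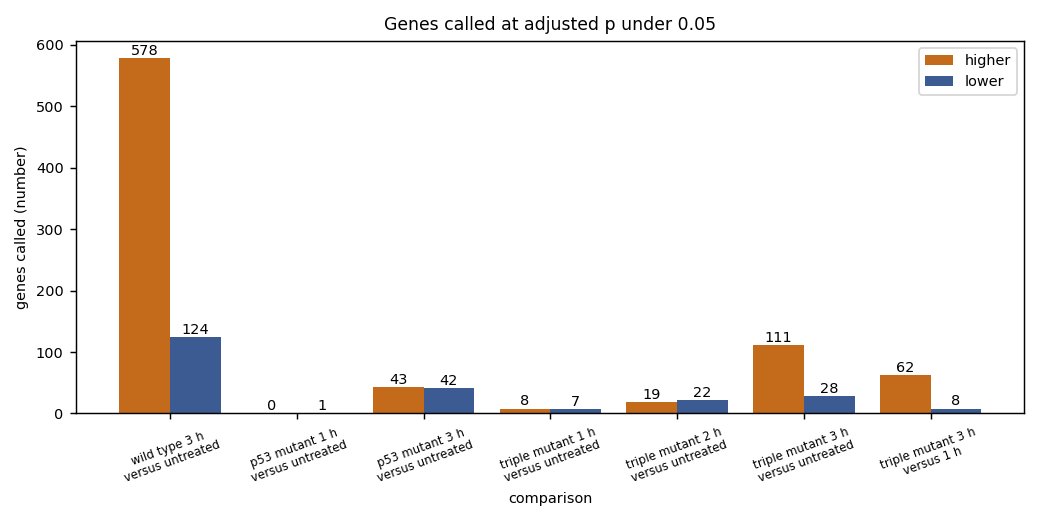
Bars give the number of genes called higher and lower at an adjusted p under 0.05 in the 7 comparisons within a genotype. Wild type embryos at 3 h have 578 rises and 124 falls, and the p53 mutant at 1 h has 0 and 1.

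The p53 target list rose in the wild type, with 19 of its 45 tested members called higher, none lower and 26 not called (22 higher adjusted over the list alone). Its test gave an adjusted p of 2.19e-15, and an adjusted p of 0.209 with an estimated correlation. No list call in any comparison held with an estimated correlation. The cell cycle arrest list had 10 of 36 members higher and 1 lower (15 and 1 adjusted over the list alone; adjusted p = 0.0022, or 0.842 with an estimated correlation). It holds the inhibitor gene cdkn2a/b, which rose by 4.89 (SE 0.376), and CDKN1B (ENSDARG00000029018), encoding an inhibitor of cyclin-dependent kinases, which rose by 2.67 (SE 0.167). Its median change was 0.23, and -0.03 with median-of-ratios scaling. Of the apoptosis list 6 of 30 rose (9 adjusted over the list alone; adjusted p = 0.000428, or 0.503 with an estimated correlation), among them the caspase gene casp8 by 3.21 (SE 0.171) and BAX, a pore-forming death gene, by 1.60 (SE 0.243). Of the 11 tested members of the interferon list 3 rose, isg15, ifit8 and isg20 (3 adjusted over the list alone; adjusted p = 0.00749, or 0.503 with an estimated correlation). isg15 also stands in the p53 target list. It rose by 2.90 (SE 0.154) and isg20 by 2.90 (SE 0.266), while ifit8 was listed at 0 in the untreated wild type and at 3.10 TPM at 3 h. Without the p53 targets, the adjusted p of the interferon, apoptosis and cell cycle arrest lists was 0.133, 0.145 and 0.145. BAX lost its call in the fit within the table (highest adjusted p = 0.101).

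Genes of mitosis fell in the wild type. Of 58 tested members of the list, 12 were called lower and none higher (16 lower adjusted over the list alone), and the median change was -0.48, or -0.75 with median-of-ratios scaling (adjusted p = 1.71e-25, or 0.209 with an estimated correlation). The spindle motor gene kif11 fell by 1.97 (SE 0.223), CDC20, an activator of the anaphase-promoting complex, by 1.89 (SE 0.181), the cyclin gene ccnb3 by 1.41 (SE 0.152) and the kinase gene aurka by 1.04 (SE 0.137). The helicase gene PIF1 fell by 2.24 (SE 0.162), cdca3 by 2.19 (SE 0.152) and CDCA7 by 2.41 (SE 0.216). Of the 58 tested S phase genes, 2 fell and 1 rose (1 higher and 8 lower adjusted over the list alone; adjusted p = 0.000199, or 0.864 with an estimated correlation), and MCM5, part of the replicative helicase, fell by 1.81 (SE 0.302). Of the 57 DNA repair genes, 6 rose and none fell (11 higher and 1 lower adjusted over the list alone; adjusted p = 0.0102, or 0.864 with an estimated correlation). They included the damage recognition gene DDB2, which rose by 1.08 (SE 0.205). The call of aurka was lost with array weights. The calls of kif11, CDC20, ccnb3, aurka, MCM5 and DDB2 were not made by the fit within the table, where their highest adjusted p values were 0.0675, 0.0571, 0.149, 0.323, 0.0973 and 0.347. DDB2 also lost its call without WT 3 h replicate 1, 3 h replicate 2 or untreated replicate 1, and MCM5 without 3 h replicate 1.

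In the p53 mutant at 3 h EGLN3, an oxygen-sensing hydroxylase, rose by 3.34 (SE 0.199, adjusted p = 1.12e-05), from 1.85 ± 0.113 to 28.2 ± 5.83 TPM. ANKRD37 rose by 2.94 (SE 0.198), DDIT4 by 2.42 (SE 0.173), and the heat shock gene hsp70l by 3.19 (SE 0.384), from 1.19 ± 0.714 to 19.6 ± 9.52 TPM. Of 28 tested heat shock genes, 3 rose and none fell (10 adjusted over the list alone; adjusted p = 3.88e-07, or 0.869 with an estimated correlation). Of the 45 p53 targets, 1 rose, DDB2 (2 adjusted over the list alone; adjusted p = 0.391, or 0.907 with an estimated correlation), and cdkn1a had a change of -0.95 (SE 0.488, adjusted p = 0.565). Of 57 DNA repair genes 1 rose (4 adjusted over the list alone, adjusted p = 2.5e-06, or 0.869 with an estimated correlation). The median change of that list was 0.39, against 0.40 in the wild type. Of 30 apoptosis genes 1 rose (3 adjusted over the list alone, adjusted p = 0.0287, or 0.869 with an estimated correlation). The rise of these 2 lists was thus not limited to genotypes with p53. The mitosis list fell here too, with 7 of 58 members lower and none higher (16 adjusted over the list alone; adjusted p = 6.21e-27, or 0.194 with an estimated correlation). CDC20 fell by 1.84 (SE 0.181), PIF1 by 2.25 (SE 0.162) and cdca3 by 2.18 (SE 0.152).

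The p53 mutant had 85 genes called at 3 h, 43 higher and 42 lower, with a median change of all genes of 0.17. The calls were 59 higher and 122 lower with median-of-ratios scaling, and 78 and 101 with quantile normalization. The fit within the table called 1 gene, and EGLN3, ANKRD37, DDIT4, hsp70l, DDB2, CDC20, PIF1 and cdca3 were not called there. Their adjusted p reached 0.3 for EGLN3, 0.92 for hsp70l and 0.454 for PIF1. DDB2 also lost its call without p53 mutant 3 h replicate 1, 3 h replicate 2 or untreated replicate 1. The count was 29 without p53 mutant 3 h replicate 1 and 231 without 1 h replicate 2, and it moved by more than 1.5 times for 13 of the 18 libraries. It was 1558 without the libraries of high 5.8S content and 8511 without those of low content. At 1 h after irradiation limma called 1 gene in the p53 mutant, PIF1, which fell by 1.35 (SE 0.162, adjusted p = 0.0499). 202 genes had an unadjusted p under 0.05, and the fit within the table called 0. PIF1 lost its call when any 1 of 16 of the 18 libraries was left out and in 11 of the other alternatives, with adjusted p up to 1. The count was 4935 without 1 h replicate 2 and 0 without 3 h replicate 1.

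The triple mutant was sampled at 3 times, and the time at which a gene was first called depends on the fit. At 1 h, bbc3 had risen by 3.10 (SE 0.198, adjusted p = 2.49e-05), cdkn1a by 3.28 (SE 0.488, adjusted p = 0.0299), PHLDA3 by 1.76 (SE 0.146, adjusted p = 0.000246) and bmb by 1.60 (SE 0.166, adjusted p = 0.0018). PIF1 had fallen by 1.99 (SE 0.162, adjusted p = 0.000246). In all, 8 genes were called higher at 1 h and all 8 were also called higher at 3 h. Another 11 were first called at 2 h, 8 of them also at 3 h, among them EXO5, a repair exonuclease, and isg15. At 3 h 95 more were called, among them mdm2 (3.80, SE 0.437, adjusted p = 0.000755), RBL2 (3.64, SE 0.32) and foxo3b (3.43, SE 0.551, adjusted p = 0.00904). A first call at 3 h does not exclude an earlier change, and mdm2 stood at 1.83 (SE 0.437, adjusted p = 0.557) at 1 h and 2.30 (SE 0.437, adjusted p = 0.0669) at 2 h. Likewise foxo3b stood at 1.24 at 1 h and 2.27 at 2 h (SE 0.551 each). The spread behind these errors is shared with the other genotypes. Between 1 h and 3 h PHLDA3 rose by 2.24 (SE 0.146, adjusted p = 3.21e-05) and isg15 by 2.41 (SE 0.154, adjusted p = 3.21e-05), whereas cdkn1a changed by 0.75 (SE 0.488, adjusted p = 1). CCNG1 rose by 1.46 (SE 0.193, adjusted p = 0.00218) at 3 h, and lost its call with median-of-ratios scaling and without untreated replicate 1 (adjusted p up to 0.234). FBXW7 had a change of 1.07 (SE 0.395, adjusted p = 0.741) at 3 h, which the fit within the table called (adjusted p = 0.000938). The calls of cdkn1a at 1 h and foxo3b at 3 h were lost when any 1 of 12 libraries (adjusted p up to 0.65) and any 1 of the 4 untreated and 3 h libraries (up to 0.123) was left out. The former was also lost with a pseudocount of 0.1 TPM, with no filter and without mitochondrial transcripts. That of bmb at 1 h was lost without 1 h replicate 2 or untreated replicate 1 (up to 0.0612). EXO5 at 2 h lost its call with quantile normalization and without 2 h replicate 1 or untreated replicate 1 (up to 0.0693), and isg15 at 2 h with a pseudocount of 5 TPM, with a replicate block and when any 1 of 8 libraries was left out (up to 0.392).

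**Figure D4:**
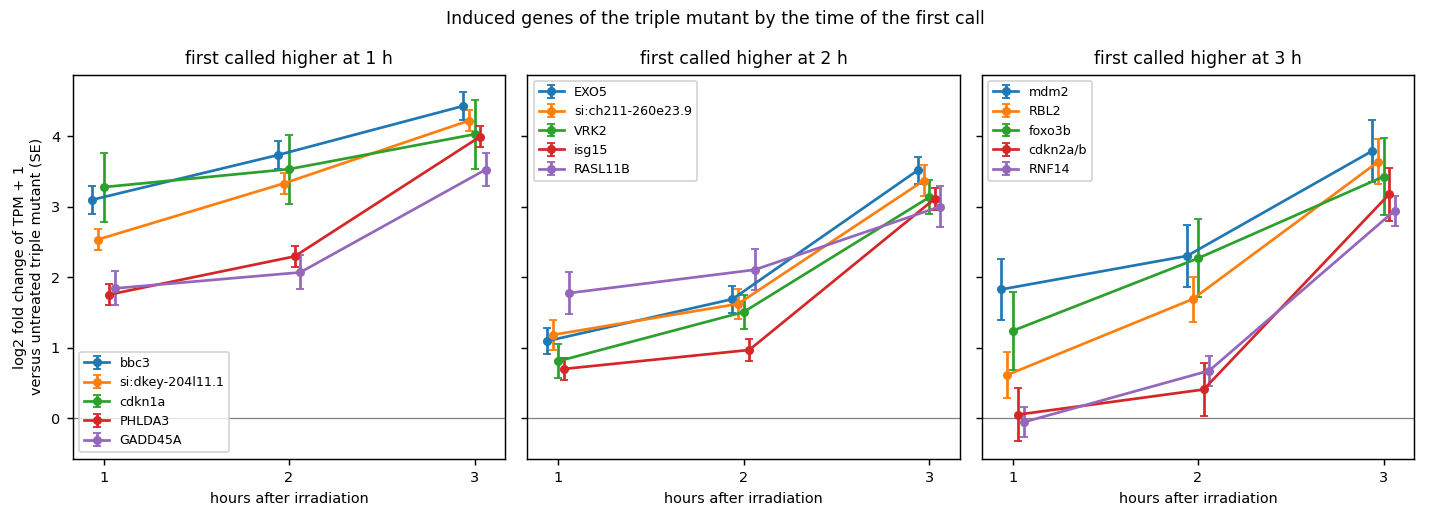
Points give the log2 fold change against the untreated triple mutant at 1, 2 and 3 h, with standard errors as bars, for 5 genes of each time of first call. bbc3 and cdkn1a stand above 3 from 1 h on, while RBL2 goes from 0.62 at 1 h to 3.64 at 3 h.

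Called members of the p53 and mitosis lists also grew in number with time in the triple mutant. Of 45 p53 targets, 4 rose at 1 h, 6 at 2 h and 14 at 3 h (8, 13 and 21 adjusted over the list alone, with 1 lower at 3 h). The adjusted p was 1.75e-12, 2.11e-08 and 2.75e-29, or 0.263, 0.433 and 0.075 with an estimated correlation. Of 36 cell cycle arrest genes, 8 rose at 3 h (15 higher and 1 lower adjusted over the list alone; adjusted p = 1.12e-13, or 0.148 with an estimated correlation), among them CDKN1B (ENSDARG00000029018) by 1.92 (SE 0.167) although cdkn1a is mutated here. The mitosis list had 2 of 58 members lower at 1 h, 7 at 2 h and 8 at 3 h (11, 18 and 20 adjusted over the list alone). The adjusted p was 4.26e-15, 2.85e-25 and 5.39e-37, or 0.263, 0.189 and 0.075 with an estimated correlation. At 3 h its median change was -0.57, and aurka fell by 1.56 (SE 0.137) and ccnb3 by 1.38 (SE 0.152). Of 58 S phase genes 3 fell at 3 h, MCM2, MCM4 and MCM5 (5 adjusted over the list alone; adjusted p = 0.000538, or 0.826 with an estimated correlation). The median change of that list was -0.02, with 28 members above 0. At 1 h and 2 h its direction was up, with medians of 0.15 and 0.33 and 0 members called (adjusted p = 0.00013 and 0.00217, or 0.76 and 0.88 with an estimated correlation). Of 30 apoptosis genes 3 rose at 3 h (4 adjusted over the list alone; adjusted p = 0.00448, or 0.556 with an estimated correlation, and 0.997 without the p53 targets). Of 11 interferon genes 3 rose at 3 h (3 adjusted over the list alone; adjusted p = 6.81e-05, or 0.148 with an estimated correlation, and 0.0255 without the p53 targets). The MCM calls were lost when any 1 of at least 10 libraries was left out, with adjusted p up to 0.546, 0.459 and 0.306. The share of mitochondrial transcripts was 4.00% and 3.57% in the untreated libraries, 2.35% and 1.70% at 1 h, 1.15% and 1.48% at 2 h, and 2.37% and 2.43% at 3 h.

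Counts in the triple mutant were 15 at 1 h (8 higher, 7 lower), 41 at 2 h (19 and 22) and 139 at 3 h (111 and 28), and 70 between 1 h and 3 h (62 and 8). Fits within the table called 456 (126 higher, 330 lower), 4077 (3097 and 980), 1147 (636 and 511) and 440 genes (297 and 143), and included the 15, 41, 139 and 70. The split of rises and falls thus depends on the fit. With median-of-ratios scaling the counts were 28, 97, 213 and 130, the last with 101 higher and 29 lower. Leaving out 1 library gave 5 (without 1 h replicate 2) to 27 (without p53 mutant 1 h replicate 1) at 1 h, and 11 (without untreated replicate 1) to 114 (without p53 mutant 1 h replicate 2) at 2 h. It gave 64 (without 3 h replicate 2) to 197 (without p53 mutant 1 h replicate 1) at 3 h, and 22 to 134 without these same libraries between 1 h and 3 h. Without the libraries of high or low 5.8S content, all of other genotypes, the counts were 421 or 427, 3977 or 3976, 1020 or 1037 and 462 or 455. Of the genes called at 1 h, 8 rises and 4 falls were also called at 3 h. In 100 simulations without an effect but with shared untreated libraries the means were 0 and 0.01 and the maxima 0 and 1. Both comparisons rest on the same 2 untreated libraries, which can add to such an overlap. The simulations held no changed genes, so they cannot show how much the shared libraries add among genes that did change.

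The responses of the genotypes were then compared directly. The wild type response at 3 h exceeded that of the p53 mutant by 6.62 (SE 0.69, adjusted p = 0.000673) for cdkn1a, 5.19 (SE 0.279, adjusted p = 1.8e-06) for bbc3 and 4.61 (SE 0.207, adjusted p = 4.33e-07) for PHLDA3. For mdm2 the difference was 4.05 (SE 0.618, adjusted p = 0.0123) and for CCNG1 1.93 (SE 0.272, adjusted p = 0.00648). The triple mutant response exceeded that of the p53 mutant by 4.28 (SE 0.207, adjusted p = 1.56e-06) for PHLDA3 and 4.04 (SE 0.279, adjusted p = 2.15e-05) for bbc3. For foxo3b the differences, 3.29 (SE 0.779, adjusted p = 0.205) and 3.27 (SE 0.779, adjusted p = 0.206), missed the threshold, as did those of FBXW7 (1.13 and 1.1, SE 0.558, adjusted p = 1) and pmaip1 (1.09 and 0.62, SE 0.321, adjusted p = 0.448 and 1). The mdm2 call was lost when any 1 of 6 libraries of the wild type and the p53 mutant was left out (adjusted p up to 0.0771), and that of CCNG1 with median-of-ratios scaling and array weights (up to 0.388). In the triple mutant minus p53 mutant difference, mdm2 (3.28, SE 0.618, adjusted p = 0.0613) and CCNG1 (1.43, SE 0.272, adjusted p = 0.0615) were not called.

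Between the triple mutant and the wild type at 3 h, EGLN3, ANKRD37 and DDIT4 were among the genes whose response differed. The triple mutant response was lower by -3.44 (SE 0.281, adjusted p = 0.000265) for EGLN3, by -3.12 (SE 0.28, adjusted p = 0.000496) for ANKRD37 and by -2.13 (SE 0.245, adjusted p = 0.00541) for DDIT4. EGLN3 stood at 27.1 ± 0.594 TPM in the wild type at 3 h and at 1.31 ± 0.184 TPM in the triple mutant, against 1.74 ± 0.339 and 1.45 ± 0.332 TPM untreated. For bbc3 and cdkn1a no difference was called (-1.16, SE 0.279, adjusted p = 0.388, and -1.63, SE 0.69, adjusted p = 0.778). DDIT4 lost its call with median-of-ratios scaling, with a replicate block and without triple mutant untreated replicate 1 (adjusted p up to 0.107).

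These differences numbered 71 for the wild type minus the p53 mutant (64 higher, 7 lower), 52 for the triple mutant minus the p53 mutant at 3 h (44 and 8), 5 at 1 h (4 and 1) and 11 for the triple mutant minus the wild type (2 and 9). The last became 3 higher and 6 lower with median-of-ratios scaling, where the median of all genes moved from -0.18 to -0.01, and 3 and 7 with quantile normalization. Leaving out 1 library gave 40 (without p53 mutant 3 h replicate 2) to 100 and 29 (without p53 mutant 3 h replicate 1) to 102, both highest without p53 mutant 1 h replicate 1. It gave 2 (without triple mutant 1 h replicate 1) to 14 (without p53 mutant 1 h replicate 2) at 1 h, and 5 (without triple mutant untreated replicate 1) to 62 (without wild type untreated replicate 1) for the last. Without the libraries of high or low 5.8S content the counts were 1439 or 358, 732 or 4405, 40 or 3863 and 2900 or 5342.

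The wild type and the triple mutant, which share no libraries, had 101 rises and 23 falls in common at 3 h. Independent calls would share 3.45 and 0.187, and the two-sided Fisher exact test across genes gave p = 2.99e-143 and 1.01e-46. Of the 101 shared rises 3 were also called in the p53 mutant, and 38 met the definition of p53-dependent induced genes. Genes are not independent replicates, and both comparisons use the same estimate of the spread per gene, so these p values overstate the evidence. With a separate fit within each table, 60 rises and 7 falls were shared. Leaving out 1 library gave 57 (without triple mutant untreated replicate 1) to 178 (without p53 mutant 1 h replicate 1) shared genes.

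Of the 38 p53-dependent induced genes, 32 were also called in the wild type minus p53 mutant difference, and 9 stand in the p53 target list. The first number is partly built in. The set was chosen for a rise in the wild type, and both differences subtract the same p53 mutant libraries. The definition also favours genes with a small change in the p53 mutant, so low values there are no separate evidence. The set holds genes with a named role in cell cycle control or cell death (cdkn1a, cdkn2a/b, RBL2, GADD45A (ENSDARG00000043581), PHLDA3, bbc3 and casp8), the repair exonuclease EXO5, sesn3 of the sestrin stress proteins, the Wnt agonist RSPO1, the kinase gene VRK2 and isg15. EXO5 rose by 3.90 (SE 0.19) in the wild type and 3.52 (SE 0.19) in the triple mutant, against 0.24 (SE 0.19, adjusted p = 0.76) in the p53 mutant. RBL2 rose by 4.19 and 3.64 against -0.06 (SE 0.32 each, adjusted p = 0.974 in the p53 mutant). casp8 rose by 3.21 and 2.55 against 0.25 (SE 0.171 each, adjusted p = 0.713), and isg15 by 2.90 and 3.11 against -0.03 (SE 0.154 each, adjusted p = 0.967). Neither mdm2, CCNG1 nor foxo3b is in the set, because their triple mutant minus p53 mutant difference missed the threshold. The set held 23 genes without p53 mutant 3 h replicate 1 and 66 without p53 mutant 1 h replicate 1. cdkn2a/b was not called in the difference with a pseudocount of 0.1 TPM, the stricter filter, either replicate block or array weights, nor when any 1 of 10 libraries was left out (adjusted p up to 0.551), and RBL2 not with a pseudocount of 0.1 TPM (up to 0.1). cdkn1a was not called in it without p53 mutant 3 h replicate 1 or triple mutant untreated replicate 1 (up to 0.0567).

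**Figure D5:**
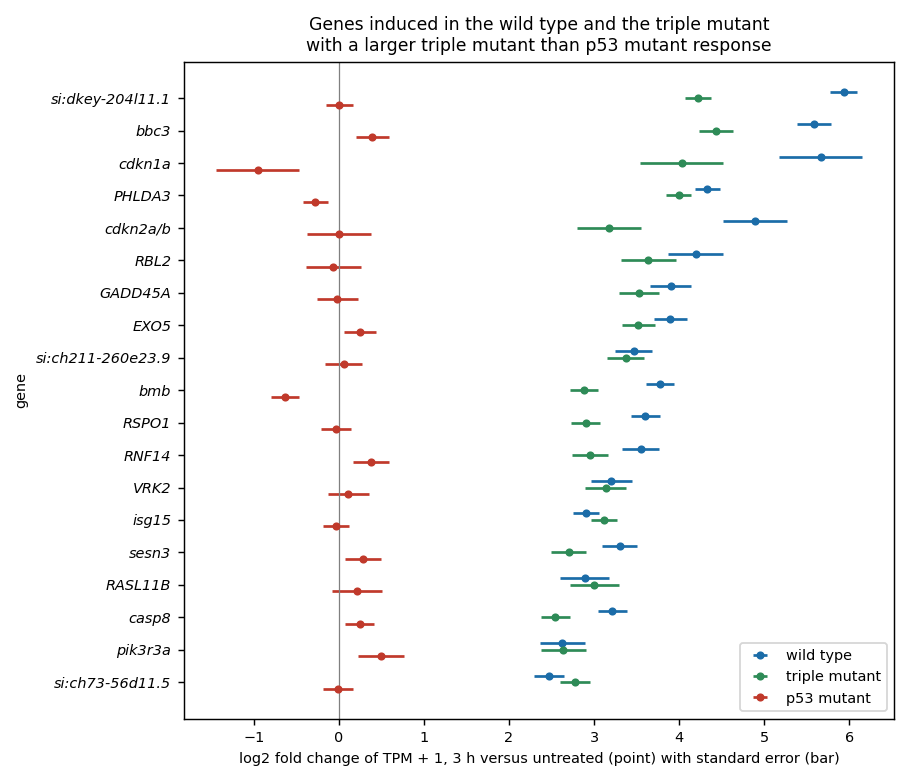
Points give the log2 fold change at 3 h in each genotype and bars its standard error, for 19 p53-dependent induced genes with a symbol and large mean changes. Wild type and triple mutant values lie above 2 for each gene, and p53 mutant values between -0.95 and 0.50 (cdkn2a/b was listed at 0 there).

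Falls were shared by all 3 genotypes, the p53 mutant included. At 3 h 13 genes were called lower in each, and they were NUSAP1, kif11, aurka, PIF1, PARPBP, ccnb3, histh1l1, KPNA2, cdca3, CDCA7, troap, CDC20 and kmt5ab. The p53 mutant shared 24 falls with the wild type (0.28 for independent calls, two-sided Fisher exact p = 1.85e-42) and 14 with the triple mutant (0.0633, p = 3.13e-31). Its rises overlapped with 25 of the wild type (1.34 for independent calls, two-sided Fisher exact p = 4.57e-27) and 3 of the triple mutant (0.257, two-sided Fisher exact p = 0.00215). In the wild type and the p53 mutant, 3 h and untreated libraries differ in 5.8S content alike, and the untreated libraries deviate together by replicate number (r = 0.63), so calls shared by these 2 genotypes can also stem from the libraries. The comparisons also use the same estimate of the spread per gene, so these p values overstate the evidence. The unknown age of untreated embryos at collection bears on calls shared by all 3 genotypes too. PIF1 went from 8.29 ± 0.636 to 0.960 ± 0.0424 TPM in the wild type, from 8.16 ± 0.764 to 0.930 ± 0.0566 TPM in the p53 mutant, and from 9.43 ± 0.113 to 0.835 ± 0.0919 TPM in the triple mutant. CDC20 went from 49.4 ± 13.0 to 12.4 ± 1.2, from 57.3 ± 3.83 to 15.3 ± 1.06, and from 44.5 ± 1.1 to 9.64 ± 0.339 TPM. In the fit within the p53 mutant table PIF1 and CDC20 were not called (adjusted p = 0.454 and 0.433).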

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

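All tests of explanations in this part were chosen only after the result was seen, except the test of preparation for mt-atp8, which was later altered as described there. The differences between responses were chosen before the data were examined.

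Differences between the responses of 2 genotypes, each tested as such, drew attention in 4 comparisons. The wild type minus the p53 mutant at 3 h gave 71 genes, with cdkn1a at 6.62, si:dkey-204l11.1 at 5.93, bbc3 at 5.19, cdkn2a/b at 4.89 (listed at 0 in the p53 mutant untreated and at 3 h), PHLDA3 at 4.61, mdm2 at 4.05 and CCNG1 at 1.93, and zgc:194285 at -2.04, epcam at -1.67 and MED11 at -1.15. DCTPP1, at -2.77, was listed at 0 in the wild type at 3 h, so its value depends on the pseudocount. The triple mutant minus the p53 mutant at 3 h gave 52 genes, with cdkn1a at 4.98, PHLDA3 at 4.28, si:dkey-204l11.1 at 4.22, bbc3 at 4.04 and RBL2 at 3.70, and EGLN3 at -3.42, ANKRD37 at -2.98, si:dkey-85k7.7 at -2.23, CCNG2 at -1.55 and vhl at -1.52. At 1 h the same difference gave 5 genes, bbc3 at 2.97, si:dkey-204l11.1 at 2.65, bmb at 2.13, PHLDA3 at 1.81 and mt-atp8 at -8.76, the last set by the pseudocount. The triple mutant minus the wild type at 3 h gave 11 genes, with EGLN3 at -3.44, ANKRD37 at -3.12, si:dkey-85k7.7 at -2.90, DDIT4 at -2.13 and P4HA1 at -1.94. Its value of 5.47 for si:dkeyp-21h4.3 also depends on the pseudocount, since the gene was listed at 0 in every triple mutant library and above 0 in the 6 libraries that hold 5.8S ribosomal RNA. Several of these calls were lost when any 1 of many libraries was left out: MED11 (15 of 18, adjusted p up to 0.388), zgc:194285 (14, up to 0.143), CCNG2 (14, up to 0.204), vhl (14, up to 0.286) and mt-atp8 (13, up to 0.37). At 3 h mdm2 was lost without any 1 of p53 mutant 3 h replicates 1 and 2, untreated replicate 2, wild type 3 h replicates 1 and 2 and untreated replicate 1 (up to 0.0771), cdkn1a (triple minus p53 mutant) without p53 mutant 3 h replicate 1 or triple mutant untreated replicate 1 (up to 0.0567), DDIT4 without the latter (up to 0.107) and P4HA1 without triple mutant 3 h replicate 2, either untreated replicate or either wild type 3 h replicate (up to 0.244). At 1 h bmb was lost without triple mutant 1 h replicate 1 or 2 or untreated replicate 1 (up to 0.869), PHLDA3 without p53 mutant untreated replicate 1 or triple mutant 1 h or untreated replicate 1 (up to 1), and these with bbc3 and si:dkey-204l11.1 also with array weights. Median-of-ratios scaling ended the calls of CCNG1, epcam, DCTPP1, MED11, vhl, DDIT4, P4HA1 and, at 1 h, PHLDA3.

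Hypoxia response genes had a median change over all 59 members of 0.51 at 3 h in the wild type, 0.29 in the p53 mutant and 0.115 in the triple mutant (0.27, 0.0851 and 0.0575 with median-of-ratios scaling, 0.39 and 0.14 in the first 2 with quantile normalization), and the 10 picked for being called higher in the wild type had 1.82, 1.11 and 0.14. Median-of-ratios scaling lowered the medians over all members, but it also moved the median of all genes in the wild type from 0.23 to -0.001. It would remove a real shift of most genes too, so the medians do not tell scaling from such a shift. As the whole cause of the 10 calls, scaling is argued against, since 6 of the 10 stayed called with median-of-ratios scaling. The other 4 lost their call because the change shrank and its error grew. They had a median of 0.60 (SE 0.28, only just over 2 errors from 0), against 0.88 (SE 0.16) as deposited. A difference between the 2 kinds of untreated library stays open: all 10 stayed called without either kind, but so did all 265 called results of named genes, and each setting leaves 1 untreated wild type library. A preparation shared by the 3 h libraries of the wild type and the p53 mutant cannot be told apart from a response that starts after 1 h: at 1 h in the p53 mutant the median of these genes was 0.0907, and of all genes -0.15. Genotype stays open too, untested apart from table and preparation.

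More genes rose than fell in the wild type at 3 h, 82.3% of those called. Scaling of the TPM values may account for this, since with median-of-ratios scaling 50.5% were higher. That scaling moved the median change of all genes to -0.001, so it would also remove a real shift of most genes, and the 2 cannot be told apart. In the triple mutant at 3 h the share was 79.9%, and 69.95% with that scaling, and the fit within the table called 636 higher and 511 lower. Without the untreated library of over 100 TPM of 5.8S ribosomal RNA the share was 74.8%, and without all 3 libraries of that kind 56.95%, settings with the same fold changes in the wild type and a different spread. Without that library the median change of all genes was 0.027, against 0.23 with it. The median TPM of tested genes was 5.57 in it, 8.1 in the other untreated wild type library, and 8.5 and 8.61 at 3 h. That library thus adds to the upward shift of all genes, to which the split of rises and falls is relative. How much of the excess of calls it accounts for stays open, since leaving it out leaves 1 untreated library. No biological explanation was tested.

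The mitochondrial transcript mt-atp8 was listed at 0 in all 4 triple mutant libraries at 1 h and 2 h, and at 367 to 560 TPM untreated and at 3 h. The other 12 mitochondrial transcripts also fell, with a median change of -1.12 at 1 h (quartiles -1.15 and -0.93) and 0 called lower. A fall in the share of mitochondrial RNA was seen, though its list was not called with an estimated correlation (camera adjusted p = 0.263). A fall of that size would leave mt-atp8 well above 0, which argues against it as the whole cause of the values of 0. For a preparation or processing that set the 1 h and 2 h libraries apart, the planned count of genes at 0 on one side and at 10 TPM or more on the other was 1, mt-atp8 itself, against 0 in both other pairings of the groups, and the test was then altered to leave that gene out because it counted the pattern's own gene. The altered count was 0 in every pairing, which leaves nothing to compare, so the planned bound decides nothing, such a cause stays open, and no biological explanation was tested.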

How the results depend on the processing

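Settings by 5.8S content, crossed replicate numbers, the 5.8S block and removal of mitochondrial transcripts were chosen only after the results were seen. Counts are of called genes, for the wild type (W), the p53 mutant at 1 h and 3 h (K1, K3), the triple mutant at 1 h, 2 h and 3 h and 3 h against 1 h (T1, T2, T3, T31), the differences wild type minus p53 mutant (WK), triple minus p53 mutant at 3 h and 1 h (TK, TK1) and triple minus wild type (TW), the wild type and triple mutant overlap (O) and the p53-dependent set (D), beside 702, 1, 85, 15, 41, 139, 70, 71, 52, 5, 11, 124 and 38. Only counts moved by over 1.5 times are listed. K1 was 0 with a pseudocount of 0.1 TPM, the stricter filter, both scalings, the separate fit, any block (replicate block, crossed replicate block, 5.8S block), the robust fit, array weights and removal of mitochondrial transcripts. The 5.8S block was fitted for K1 alone, without the 3 h libraries of the wild type and the p53 mutant, so no other count was checked with it. Pseudocount 5 TPM gave T31 109, TK 82 and D 59. No filter gave TW 25. The stricter filter gave T31 44, WK 44 and D 25. Median-of-ratios scaling gave K3 181, T1 28, T2 97, T3 213, T31 130, TK 88, TK1 9 and D 63. Quantile normalization gave K3 179, T1 30, T2 118, T3 224, T31 130, TK 106, TK1 9, O 188 and D 64. The separate fit gave W 91, K3 1, T1 456, T2 4077, T3 1147, T31 440 and O 67. The replicate block gave TW 5. Array weights gave W 174, T1 238, T2 7138, T3 3281, T31 375, WK 47, TK 185, TK1 1 and D 67. A required log2 change of 1 gave W 333. Without the 3 libraries of high 5.8S content the counts were W 5247, K1 19, K3 1558, T1 421, T2 3977, T3 1020, T31 462, WK 1439, TK 732, TK1 40, TW 2900, O 468 and D 148. Without the 3 of low content they were W 10552, K1 6151, K3 8511, T1 427, T2 3976, T3 1037, T31 455, WK 358, TK 4405, TK1 3863, TW 5342, O 695 and D 149. In these settings, and when 1 library was left out, a group may hold a single library, which is assumed to vary like the others. Leaving out 1 library gave W 172 to 1900, K1 0 to 4935, K3 29 to 231, T1 5 to 27, T2 11 to 114, T3 64 to 197, T31 22 to 134, WK 40 to 100, TK 29 to 102, TK1 2 to 14, TW 5 to 62, O 57 to 178 and D 23 to 66.

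Libraries of the same replicate number did not deviate together throughout. Deviations from the group mean correlated at 0.79 between p53 mutant untreated and 1 h, and at 0.7 and 0.63 between these and the untreated wild type, the 3 groups whose replicates differ in 5.8S content. The triple mutant at 1 h, with 5.8S listed at 0, correlated with these at 0.5, 0.39 and 0.37, so 5.8S content does not cover every alignment of the numbers. The correlation was 0.04 between p53 mutant untreated and 3 h, -0.1 between triple mutant untreated and 3 h and -0.34 between wild type untreated and 3 h, so pairing was not assumed. With an estimated correlation camera called 0 lists in all 11 comparisons. Without the p53 targets it called 9 lists in W, against 14, and 7 in WK, against 11. In WK the apoptosis list changed direction without them (adjusted p = 0.918). Of 265 called results of named genes, none changed direction, and 102 lost their call when some single library was left out. The call was lost for 20 and 12 with pseudocounts of 0.1 and 5 TPM, 16 with no filter, 1 of 233 with the stricter filter, 6 in the robust fit, 13 with the crossed replicate block, 22 of 261 without mitochondrial transcripts, 53 with median-of-ratios scaling, 35 with quantile normalization, 74 of 209 in the separate fit, 41 with array weights and 26 with the replicate block.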

Other observations

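The hypoxia list in this part, and its tests, were chosen only after the result was seen. The other lists were fixed before.

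Genes of the response to low oxygen rose in the wild type and the p53 mutant at 3 h, and fewer in the triple mutant. Of 59 tested members of the list, 10 rose in the wild type (24 adjusted over the list alone; p = 1.79e-09, or 0.154 with an estimated correlation). In the p53 mutant 5 rose (8 higher and 1 lower adjusted over the list alone; p = 0.00015, or 0.352 with an estimated correlation). In the triple mutant 1 rose, DDIT4 (1 higher and 1 lower adjusted over the list alone; p = 0.316, or 0.801 with an estimated correlation). The triple mutant minus wild type difference called 4 of the 59 lower and none higher (6 adjusted over the list alone; p = 4.44e-10, or 0.141 with an estimated correlation), among them P4HA1, a collagen hydroxylase, by -1.94 (SE 0.241). P4HA1 lost its call with median-of-ratios scaling, with a replicate block and when any 1 of 5 libraries was left out (adjusted p up to 0.244). These p values are not adjusted over lists.

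Tissue marker genes gave list results that differed between genotypes and times. Lens genes had a median change of -0.67 in the wild type at 3 h, with 2 of 28 lower (8 adjusted over the list alone; adjusted p = 5.3e-22, or 0.209 with an estimated correlation). In the p53 mutant the median was -0.62, with 1 lower (4 adjusted over the list alone; adjusted p = 2.03e-21, or 0.194 with an estimated correlation) and in the triple mutant 0.09 (adjusted p = 0.964). The triple mutant minus wild type difference had a median of 0.78 (2 higher adjusted over the list alone; adjusted p = 2.07e-23, or 0.448 with an estimated correlation). At 1 h the direction was the reverse. The lens median was 0.38 in the p53 mutant (adjusted p = 4.05e-31, or 0.168 with an estimated correlation) and -0.25 in the triple mutant (adjusted p = 4.34e-06, or 0.662 with an estimated correlation). The triple mutant minus p53 mutant difference was -0.62 at 1 h (adjusted p = 9.8e-29, or 0.204 with an estimated correlation) and 0.70 at 3 h (adjusted p = 1.23e-15, or 0.255 with an estimated correlation). No lens gene was called at 1 h in either, over all genes or adjusted over the list alone. The 1 h value of the p53 mutant rests on the library pair of lowest agreement (r = 0.907). In the wild type and the p53 mutant, 3 h and untreated libraries differ in ribosomal RNA content, as described above. The triple mutant libraries do not. The lens falls at 3 h, and their differences from the triple mutant, can therefore also stem from the libraries rather than from genotype. Muscle genes had a median of -0.74 in the p53 mutant at 3 h, with 1 of 38, pvalb1, called lower (1 higher and 20 lower adjusted over the list alone; adjusted p = 4.6e-31, or 0.194 with an estimated correlation). The pvalb1 call was lost with median-of-ratios scaling, in the fit within the table, with a replicate block and without p53 mutant 3 h replicate 1, 3 h replicate 2 or untreated replicate 1 (adjusted p up to 1). Epidermis genes had a median of -0.40 in the triple mutant at 3 h, with none of 34 called over all genes or adjusted over the list alone (adjusted p = 9.56e-13, or 0.148 with an estimated correlation). The median was already -0.41 at 1 h and -0.42 at 2 h (adjusted p = 3.35e-10 and 1.69e-10, or 0.263 and 0.189 with an estimated correlation). These comparisons share the same untreated libraries, which can add to a shift seen at every time. The triple mutant minus p53 mutant difference for muscle genes had a median of 0.94 (19 higher adjusted over the list alone; adjusted p = 1.62e-29, or 0.243 with an estimated correlation). These medians kept their sign under both scalings.

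Among stress lists in the wild type at 3 h, 2 of 28 heat shock genes rose (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.015, or 0.864 with an estimated correlation). Of 31 antioxidant genes 3 rose (5 adjusted over the list alone; adjusted p = 0.0396, or 0.351 with an estimated correlation, and 0.117 without the p53 targets). Mitochondrial transcripts had a median change of -0.59 in the wild type at 3 h, with all 13 below 0 and none called over all genes or adjusted over the list alone (adjusted p = 0.000149, or 0.842 with an estimated correlation). The median was -0.81 in the triple mutant at 3 h (adjusted p = 3.98e-05, or 0.556 with an estimated correlation) and 0.67 in the p53 mutant (adjusted p = 0.284, or 0.907 with an estimated correlation). Single untreated libraries carry the wild type and p53 mutant values: the mitochondrial share was 2.66% and 8.06% in untreated wild type replicates 1 and 2, against 3.84% and 2.48% at 3 h, and 1.67% and 5.21% in the untreated p53 mutant, against 4.5% and 4.75% at 3 h. The light-responsive gene cry5 rose by 1.72 (SE 0.211) in the wild type, where the fit within the table did not call it (adjusted p = 0.0587).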
